A study of Mus musculus with 6 samples.

How the data were processed

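Messenger RNA libraries of the mouse line 4T1 were analysed, 3 labelled LV2 and 3 labelled in9 in the series. The 1 table used held TPM values for 56448 genes as deposited by the authors, with 2 decimals, beside a mean column per group. Per the submitters' processing notes the genome was mm10, and the aligner, the quantifier and the annotation are not given in the sources used here. Read counts were not available, so depth per sample and counting error are unknown, and no count model was used.

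The table was checked before use. Its group-mean columns equalled the means of the libraries within 3.33e-05, no pair of libraries was identical, and 16 housekeeping genes were above 0 in all libraries. Of the genes listed, 961 were assembled loci without a symbol. Coordinates, gene classes and 3' UTR came from GENCODE M21, which matched 55141 identifiers and gave a 3' UTR for 21016 genes.

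Genes with a mean TPM of at least 1 over the 6 libraries were tested (13406 genes). Values were taken as log2(TPM + 1) and fitted with limma 3.58.1 in R 4.3.3 with an intensity trend in the prior variance, as in9 minus LV2, without a replicate block. Tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05. Tables were prepared with python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

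Named genes were chosen by a rule with 3 parts. The first took the miR-9 host genes and the literature targets. The second took, per direction, the 12 called genes with the largest log2 fold change whose groups did not overlap, whose mean TPM reached 5 in the higher group and whose symbol was not a clone or predicted name. The last took up to 4 tested members of each list with the smallest p-values, and the members behind a count of 5 or fewer. Some genes that the rule takes are not reported here. The comparisons, the gene lists, this rule and the alternatives were fixed before the data were examined, except where the closing section says otherwise. Of 40 lists, 33 had at least 5 tested members and were tested with camera in limma at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. With the rotation test fry 11 of the 33 lists had an adjusted p under 0.05. None of these 11 was among the 5 lists that camera called lower. Fry tests a list against no change and was run without scaling, where the median over all tested genes was 0.06. That offset works toward higher lists and against lower ones. Beside each list the text gives the count of members called over all genes and the count when p-values were adjusted over the list alone.

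Sites of miR-9 were searched in the longest annotated 3' UTR of each gene as the 7-base matches of the seed or the 8-base match that joins them. Genes with sites were compared with genes without sites by camera, with 100 shuffled seeds of the same bases out of 104 possible, and with genes matched on 3' UTR length and expression. Annotation terms carried by the table with 10 to 500 tested genes were tested for enrichment among called genes by a one-sided Fisher's exact test.

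The steps were tested on simulated data with 13406 genes, of which 200 were changed, in 10 runs. The changed genes were drawn from those with a mean TPM above about 5, so the recovery of lower genes was not measured. Of genes changed 1.5-fold 60.3% were recovered and of genes changed 2-fold 85.2%, and 4.3% of calls were false. A list of genes raised at least 1.5-fold was called in 10 of 10 runs and an unshifted list in 0. That rise is larger than the median change of any list called in the data, so calling of smaller shifts was not measured. The simulated genes varied independently, so these rates leave out correlation between genes and any library that stands apart. Alternatives were a pseudocount of 0.1, no filter or a minimum mean TPM of 5, trimmed-mean scaling (30% of M and 5% of A trimmed), quantile normalization, no intensity trend, library weights, a replicate block, protein-coding genes only, a log2 fold change of at least 1, and leaving out each library. Values without mitochondrial transcripts and the enrichment of terms under each alternative were added after the data were seen.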

Results

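Messenger RNA was sequenced from 4T1 cells, a line derived from a mouse mammary carcinoma and cultured in medium with fetal bovine serum. The protocol for RNA extraction mentions tissue and the design text a microarray, although the other labels and the values describe sequenced cells in culture. The series describes stable knockdown of the microRNA miR-9 by lentivirus with a control group. There were 6 libraries, 3 labelled in9 and 3 labelled LV2. The labels do not spell out either name or say which group is the control, so every difference is given as in9 minus LV2 for the libraries so labelled. The values were TPM, which keep no record of sequencing depth, so the depth is unknown. Between 20123 and 20538 genes had a value above 0 in a library, and between 13154 and 13466 reached a TPM of at least 1. Libraries of one group correlated across genes at a Pearson r of 0.969 to 0.974, and libraries of different groups at 0.965 to 0.973. Nothing states that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

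The knockdown target itself could not be read from these libraries, because mature microRNA is not measured by messenger RNA sequencing. The precursor genes Mir9-1, Mir9-2 and Mir9-3 and the transcript Mir9-3hg were listed at 0 in all 6 libraries. The long non-coding RNA C130071C03Rik (chromosome 13, positions 83721381 to 83884194 in mm10), whose gene contains Mir9-2, had a TPM of 1.70 ± 0.0551 in LV2 and 1.91 ± 0.119 in in9 (SD, n = 3). Its log2 fold change was 0.10 ± 0.14 (SE) with an adjusted p of 0.715 in limma. The labels were therefore not checked against the level of miR-9.

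The first comparison asked which transcripts differed between the in9 and the LV2 cells. The named genes with the largest rises were U90926, Aqp5 and Dmkn, and those with the largest falls were Hspa1b and Hspa1a, a pair of inducible heat-shock genes. Of 13406 genes tested, 110 were higher and 26 were lower in in9 at an adjusted p under 0.05 in limma. Most changes were small: the median fold of the higher genes was 1.44 and that of the lower genes 0.762, and 16 higher and 4 lower genes reached a log2 fold change of 1 in size. At an unadjusted p under 0.05 there were 1828 higher and 785 lower genes. After trimmed-mean scaling between libraries the split was 45 higher and 25 lower, that is 64.3% higher against 80.9% without it. The median log2 fold change of all tested genes was -0.01 with that scaling and 0.06 without it. In9 replicate 1 stood apart from the other in9 libraries on the first principal component, at -2.70 against 26.1 and 27.8, with LV2 between -22.2 and -6.98. Without that library 971 genes were higher and 509 lower, and without any other single library 6 to 10 were higher and 1 to 4 lower.

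The largest rise among the named genes was in U90926 (chromosome 5, positions 92209893 to 92215408), from a TPM of 1.73 ± 0.455 to 21.9 ± 1.26 (SD, n = 3), a log2 fold change of 3.08 ± 0.14 (SE, adjusted p = 0.000689). The water channel gene Aqp5 rose from 1.32 ± 0.165 to 7.08 ± 1.44 TPM, and Dmkn, which encodes the secreted protein dermokine, from 2.59 ± 0.244 to 10.3 ± 0.893 TPM. Spp1, the gene of the secreted phosphoprotein osteopontin, was far more abundant and rose from 275 ± 5.95 to 577 ± 8.92 TPM (log2 fold change 1.07 ± 0.04, adjusted p = 0.000343). Nos2, the inducible nitric oxide synthase, rose from 21.8 ± 1.62 to 52.6 ± 8.96 TPM. The integrin subunit gene Itgb7 rose from 8.02 ± 1.32 to 20.7 ± 2.78 TPM and the endocytic receptor gene Lrp1 from 27.3 ± 2.10 to 57.8 ± 8.34 TPM. Ly6a, a surface antigen gene, rose from 2.30 ± 0.0954 to 5.87 ± 0.976 TPM. The other genes of this group, Il6, Tnc, Lcn2 and Gbp2, had log2 fold changes of 1.09, 1.05, 1.05 and 1.04. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes such as U90926 and Aqp5.

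**Figure D1:**
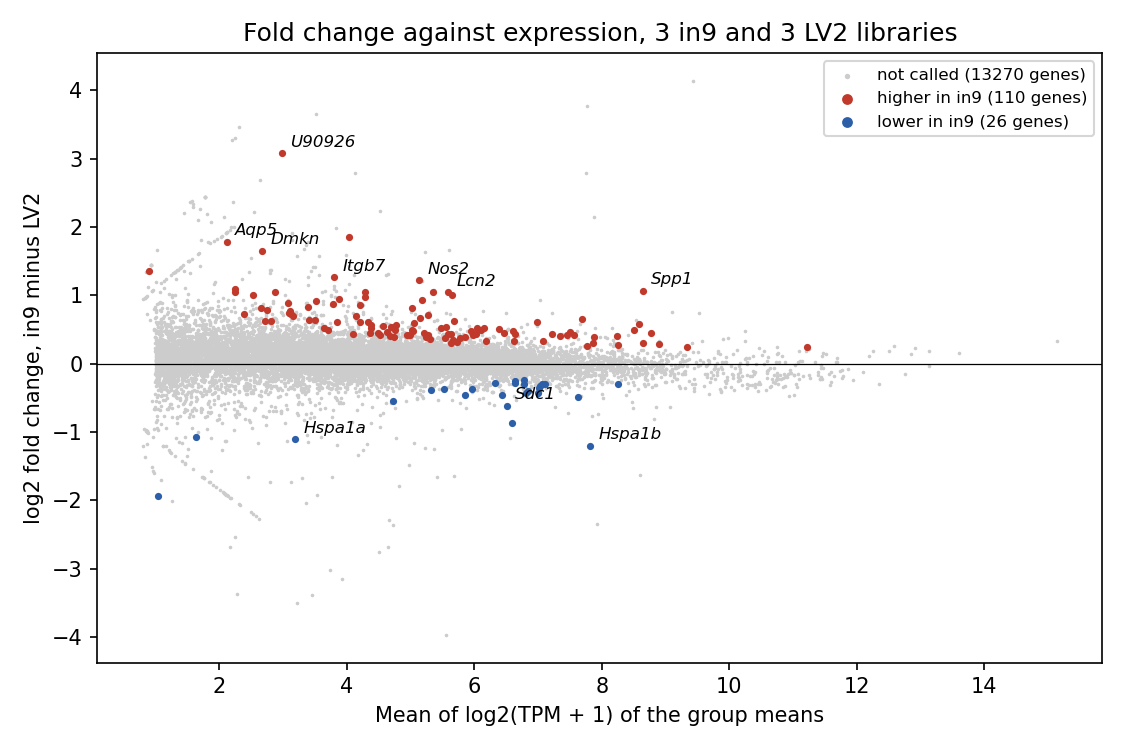
Each point is 1 of the 13406 genes tested. The horizontal axis is the mean over the groups of log2(mean TPM + 1), and the vertical axis is the log2 fold change, in9 minus LV2. The 110 higher genes (red) and the 26 lower genes (blue) at an adjusted p under 0.05 lie among uncalled genes (grey) that in places have larger but more variable changes.

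Of the genes of the type I interferon response, 11 were called higher. Of the 35 tested members of this list, 34 had a positive log2 fold change, with a median of 0.47, and none was called lower. Adjusted over the list alone, 29 were higher. The called members included the guanylate-binding protein genes Gbp2, Gbp3 and Gbp7, the transcription factors Irf7 and Stat2, the nucleic acid sensor gene Zbp1, and Ifit1, Oas2, Cmpk2 and Ifi44. Those other than Gbp2, Irf7, Zbp1 and Gbp3 were named after their values were seen. Irf7 had a log2 fold change of 0.61 ± 0.07 (SE). Zbp1 rose from 25.2 ± 1.08 to 49.2 ± 7.31 TPM, and Gbp2 from 12.6 ± 1.06 to 27.0 ± 1.04 TPM (SD, n = 3). The list ranked higher than the other genes by camera (adjusted p = 1.41e-17), with an adjusted p = 0.312 with an estimated correlation. Each in9 library had a list median above each LV2 library. The count of 11 fell to 1 or 0 when any library other than in9 replicate 1 was left out, and it was 24, with 1 lower, without in9 replicate 1. After trimmed-mean scaling it was 5.

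**Figure D2:**
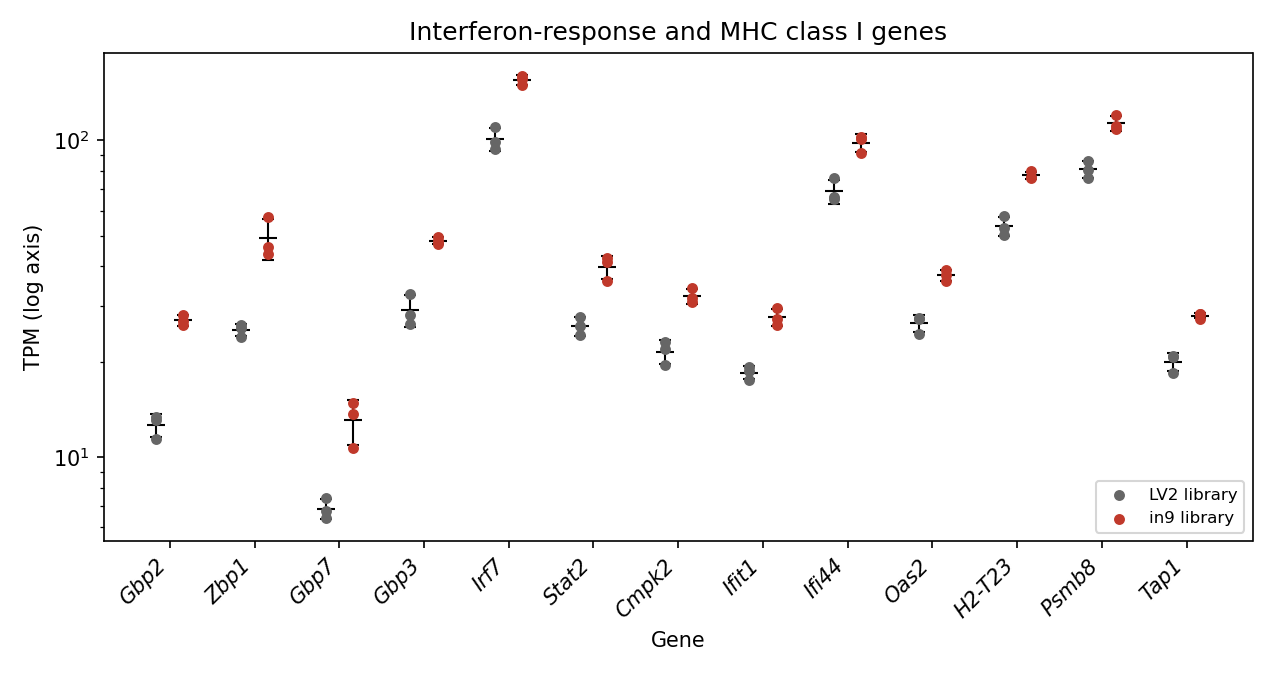
TPM (log axis) of 10 of the called interferon-response genes and the 3 called MHC class I genes in each library. Points are libraries, bars are mean ± SD of 3 libraries. For each gene the 3 in9 libraries lie above the 3 LV2 libraries, as for Gbp2, with 27.0 against 12.6 TPM on average.

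Genes of MHC class I presentation, which load and display peptides at the cell surface, moved in the same direction. All 20 tested members had a positive log2 fold change. Their median was 0.22, and 0.15 after trimmed-mean scaling, against 0.06 and -0.01 over all tested genes. The class I gene H2-T23 (log2 fold change 0.52 ± 0.06 SE), the immunoproteasome subunit gene Psmb8 (0.48 ± 0.06) and the peptide transporter gene Tap1 (0.47 ± 0.07) were called, and none was lower. Adjusted over the list alone, 13 were higher. The light chain gene B2m, at 1589 ± 41.1 TPM in LV2 and 1876 ± 50.6 TPM in in9, did not pass the test over all genes (adjusted p = 0.0547). The list was called higher by camera (adjusted p = 4.46e-07), with an adjusted p = 0.312 with an estimated correlation. The count of 3 was 9 without in9 replicate 1 and 0 without any other single library. After trimmed-mean scaling none of the 20 was called in limma, and 7 were higher adjusted over the list alone. The class I genes and the Gbp genes belong to families of similar sequence, so reads may have been split between their members.

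Of 26 tested NF-kB and inflammatory mediator genes, 4 were higher and none lower, and 7 were higher and 1 lower adjusted over the list alone. These 4 were the iron-binding protein gene Lcn2, from 32.5 ± 2.29 to 68.1 ± 2.45 TPM, the cytokine gene Il6, from 2.24 ± 0.286 to 5.92 ± 0.685 TPM, the growth factor gene Csf3, from 429 ± 8.82 to 525 ± 20.9 TPM, and the chemokine gene Cxcl5, from 313 ± 33.0 to 469 ± 33.3 TPM (SD, n = 3). The list did not rank above other genes by camera (adjusted p = 0.374), while fry, which tests a list against no change, gave an adjusted p of 0.00512. Its median log2 fold change was 0.02, and -0.05 after trimmed-mean scaling. The count of 4 was 7 without in9 replicate 1, 1 without any other single library and 2 after trimmed-mean scaling. In the list of JAK-STAT signalling genes 23 of 26 tested members had a positive log2 fold change. Only Socs3, a feedback inhibitor of cytokine signalling, was called there (0.54 ± 0.08, adjusted p = 0.0453, and 0.0526 after trimmed-mean scaling), and 11 were higher adjusted over the list alone, a count that was 1 without LV2 replicate 2 or 3, 4 without in9 replicate 2 and 3 without in9 replicate 3. That list was called higher by camera (adjusted p = 0.000431), with an adjusted p = 0.468 with an estimated correlation and of 0.0537 with fry. Among 12 tested immune modulator genes Nos2 was called, 11 were positive, and the list was called higher (adjusted p = 0.00166), with an adjusted p = 0.365 with an estimated correlation. Without in9 replicate 1 the counts of called genes in these lists were 5 and 4, and without any other single library 0.

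Genes of the extracellular matrix and its proteases changed in part. Of 23 tested members 5 were higher and none lower: Spp1, the matrix metalloproteinase genes Mmp3 (log2 fold change 1.01 ± 0.04 SE), Mmp13 (0.98 ± 0.08) and Mmp9 (0.53 ± 0.07), and the collagen gene Col5a1 (0.42 ± 0.06). Adjusted over the list alone, 8 were higher and 3 lower. The count of 5 was 9, with 3 lower, without in9 replicate 1, and 3 or 2 without any other single library. Mmp3 rose from 34.5 ± 0.327 to 70.4 ± 0.862 TPM and Mmp13 from 12.9 ± 1.29 to 26.4 ± 1.05 TPM. The list was called higher by camera (adjusted p = 0.0114), with an adjusted p = 0.414 with an estimated correlation. Of 10 tested mesenchymal genes, the matrix genes Tnc (4.07 ± 0.196 to 9.50 ± 0.402 TPM) and Sparc (54.0 ± 0.713 to 72.1 ± 1.75 TPM) were higher (Sparc with an adjusted p of 0.0247, and 0.0526 after trimmed-mean scaling), and 5 were higher adjusted over the list alone (3 without LV2 replicate 2 or 3 or in9 replicate 2 or 3). Fibronectin, Fn1, was at 237 ± 7.24 TPM in LV2 and 341 ± 37.1 TPM in in9 and missed the threshold (adjusted p = 0.0508). The vimentin gene Vim, also on the mesenchymal list, was the 1 member lower at an unadjusted p under 0.05 and was not called. It was at 3174.8 to 3331.5 TPM in LV2 and 2855.9 to 3083.5 TPM in in9. The mesenchymal list was called higher (adjusted p = 0.0456), with an adjusted p = 0.468 with an estimated correlation, and its adjusted p was 0.196 without in9 replicate 1. Without in9 replicate 1 the mesenchymal list held 3 higher and 1 lower gene, and without any other single library 0. Of 22 tested epithelial genes none was called in limma, with 1 higher and 4 lower at an unadjusted p under 0.05. The 1 higher was the E-cadherin gene Cdh1, at 118.18 to 130.37 TPM in LV2 and 129.85 to 147.13 TPM in in9. The adhesion gene Epcam was at 45.8 ± 1.90 TPM in LV2 and 36.9 ± 1.14 TPM in in9 and was the 1 gene lower adjusted over the list alone. The epithelial list was called lower (adjusted p = 0.0456), with an adjusted p = 0.414 with an estimated correlation and of 0.107 without in9 replicate 1. With fry its adjusted p was 0.346.

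Of 22 tested hypoxia-response genes 5 were higher and none lower, namely the mitophagy receptor gene Bnip3 (163 ± 2.32 to 259 ± 26.3 TPM), Ankrd37, Mxi1, Ddit4 and Ndrg1 (373 ± 6.77 to 511 ± 46.5 TPM). Adjusted over the list alone, 12 were higher (6 to 17 without 1 library, the fewest without LV2 replicate 2 and the most without in9 replicate 1), and the list was called higher (adjusted p = 2.61e-06), with an adjusted p = 0.414 with an estimated correlation. The median difference from the LV2 mean was 0.13 in in9 replicate 1 against 0.37 and 0.30 in the other in9 libraries. The count of 5 was 0 when any library other than in9 replicate 1 was left out and 13, with 1 lower, without that one, and it was 1 after trimmed-mean scaling. No glycolysis gene was called in limma over all genes, where 14 of 22 were higher at an unadjusted p under 0.05, and 11 were higher adjusted over the list alone. The pyruvate kinase gene Pkm had a log2 fold change of 0.18 (0.10 after trimmed-mean scaling) and the enolase gene Eno2 of 0.72. The median of the glycolysis list was 0.17, and 0.09 after trimmed-mean scaling. No gene of fatty acid oxidation was called in limma, with 10 of 18 higher at an unadjusted p under 0.05 and 10 higher adjusted over the list alone, among them the dehydrogenase genes Acadl (0.23) and Acadm (0.37), a count that was 5 without LV2 replicate 2 and 6 without in9 replicate 3. No cholesterol synthesis gene was called in limma, with 12 of 23 higher at an unadjusted p under 0.05 and 4 higher adjusted over the list alone, among them Idi1 (0.38) and Hmgcs1 (0.37). The cholesterol count of 4 was 11 without LV2 replicate 1, 9 without in9 replicate 1 and 0 without any other single library. The glycolysis, fatty acid oxidation and cholesterol lists were each called higher by camera (adjusted p = 8.47e-06, 0.000402 and 0.000175), and their adjusted p with an estimated correlation was 0.414, 0.312 and 0.458. With fry their adjusted p was 0.018, 0.00125 and 0.0537. Among 23 tested antioxidant genes, Nfe2l2, which encodes the regulator NRF2, was called (0.31 ± 0.05, adjusted p = 0.0453, and 0.0638 after trimmed-mean scaling), and 7 were higher and 1 lower adjusted over the list alone, with 0 to 3 higher without any single library other than in9 replicate 1. That list was called higher (adjusted p = 0.0456), with an adjusted p = 0.414 with an estimated correlation and of 0.303 without in9 replicate 1. Without that library 12 glycolysis, 5 fatty acid oxidation, 4 cholesterol and 3 antioxidant genes were higher and 2 antioxidant genes lower, and without any other single library none of these 4 lists held a called gene in limma. After trimmed-mean scaling the counts higher adjusted over the list alone were 5, 5, 2 and 1 for these lists in the same order.

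**Figure D3:**
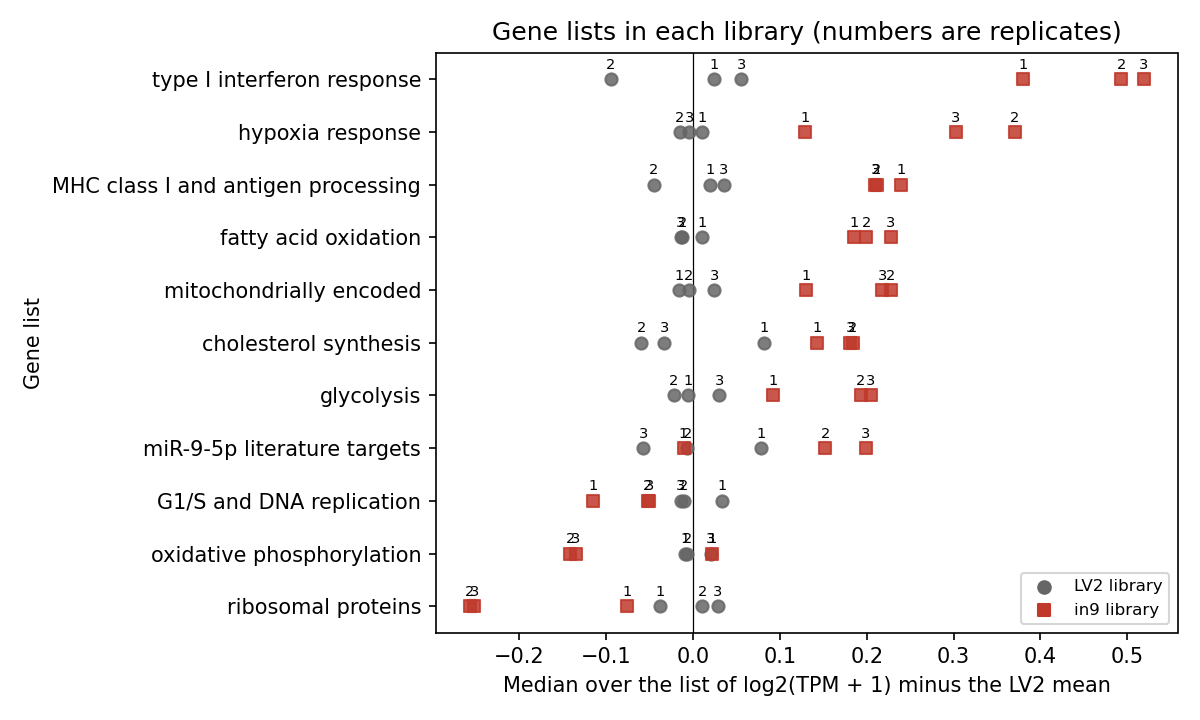
For 11 gene lists, the median over list members of log2(TPM + 1) minus the LV2 mean in each library. Circles are LV2 and squares in9 libraries, with the replicate number above each. The interferon list lies at 0.38 to 0.52 in in9, and in9 replicate 1 lies nearer to LV2 than the other in9 libraries for the ribosomal list (-0.08 against -0.26 and -0.25).

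The strongest falls among the named genes were in Hspa1b and Hspa1a, adjacent genes on chromosome 17 that encode the same inducible heat-shock protein. Hspa1b (positions 34956436 to 34959238) fell from 341 ± 12.6 to 148 ± 3.66 TPM (log2 fold change -1.20 ± 0.04 SE, adjusted p = 0.000343), and Hspa1a (positions 34969190 to 34972156) from 12.4 ± 0.718 to 5.23 ± 0.330 TPM. The copies are nearly identical, so the level of each alone is uncertain, while their summed TPM was 342 to 367 in LV2 and 151 to 157 in in9. The heparan sulfate proteoglycan gene Sdc1 fell from 112 ± 2.89 to 72.7 ± 2.19 TPM and the immediate early transcription factor gene Egr1 from 31.0 ± 2.73 to 20.8 ± 1.09 TPM (SD, n = 3). Other named genes that fell had smaller changes. They included the poly(A)-binding protein gene Pabpc4 (log2 fold change -0.49), Ssna1 (-0.47), the prolactin family gene Prl2c3 (-0.45), Arl6ip5 (-0.42), Atrnl1 (-0.40), Dph3 (-0.37) and the ubiquitin ligase subunit gene Rbx1 (-0.37). Prl2c3 has close relatives in the genome and may share reads with them. Of 22 tested genes of the immediate early and dissociation response, Hspa1b, Hspa1a and Egr1 were lower and none was higher, with 5 higher and 5 lower adjusted over the list alone. The count of 3 was 2 without in9 replicate 2 and 1 without any LV2 library or in9 replicate 3, and without in9 replicate 1 there were 2 higher and 4 lower. That list was not called by camera (adjusted p = 0.113), and its median of 0.01 turned to -0.07 after trimmed-mean scaling and -0.02 after quantile normalization. 

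Ribosomal protein genes had small negative changes in in9. All 34 tested members had a negative log2 fold change, with a median of -0.19, which was -0.09 after quantile normalization and -0.27 after trimmed-mean scaling. None was called in limma over all genes, though 27 were called without in9 replicate 1. With all libraries 26 were lower at an unadjusted p under 0.05, and 26 were lower adjusted over the list alone. That last count was 32 without in9 replicate 1, 0 without any other single library and 0 after quantile normalization. Rpl8 was at 2204 ± 56.1 TPM in LV2 and 1954 ± 70.6 TPM in in9, and Rplp1 at 5787 ± 164 and 4713 ± 509 TPM. The ribosomal list was called lower by camera (adjusted p = 5.66e-19), with an adjusted p = 0.414 with an estimated correlation. With fry, which tests against no change, its adjusted p was 0.0716. Ribosomal protein genes held 12.7%, 13.2% and 13.3% of all TPM in LV2 and 12.4%, 10.4% and 10.6% in in9. Transcripts of the mitochondrial chromosome held 5.90%, 5.97% and 6.01% in LV2 and 6.42%, 7.64% and 7.49% in in9. More than 3% of all TPM was the 1 short gene mt-Atp8, singled out after its values were seen, at 32097 ± 356 TPM in LV2 and 40494 ± 5913 TPM in in9 (adjusted p = 0.179), so most of the difference in share lay in a gene that was not called. Of the 13 mitochondrially encoded genes mt-Nd4 was called higher (0.25 ± 0.04), 7 were higher adjusted over the list alone, and the list was called higher (adjusted p = 0.000575), with an adjusted p = 0.312 with an estimated correlation. Nuclear genes of oxidative phosphorylation had a median of -0.10, and none of 27 was called in limma, with 2 higher and 5 lower at an unadjusted p under 0.05 and none adjusted over the list alone. In9 replicate 1 had a list median of 0.02 from the LV2 mean against -0.14 in each of the other in9 libraries, and the median of -0.10 was -0.06 without in9 replicate 3 and -0.17 after trimmed-mean scaling. That list was called lower (adjusted p = 0.000338), with an adjusted p = 0.458 with an estimated correlation and of 0.269 with fry. Genes of the G1/S transition had a median of -0.07 over 26 members. None was called in limma, with 1 higher and 5 lower at an unadjusted p under 0.05, and 2, Tyms (-0.38) and Mcm6 (-0.23), were lower adjusted over the list alone. After trimmed-mean scaling the median was -0.14, with 1 called lower and 6 lower adjusted over the list alone. Without that scaling, the count of 2 adjusted over the list alone was 0 or 1 without any single library other than in9 replicate 1. The G1/S list was called lower (adjusted p = 0.0001), with an adjusted p = 0.312 with an estimated correlation and of 0.0633 with fry. Genes of the integrated stress response had a median of -0.05, with none of 22 called in limma and 6 lower at an unadjusted p under 0.05. The list was called lower by camera (adjusted p = 0.00682), with an adjusted p = 0.458 with an estimated correlation and of 0.304 with fry. Its median turned to 0.03 without LV2 replicate 1, and after trimmed-mean scaling it was -0.13 with 6 lower adjusted over the list alone. The count of mitochondrially encoded genes called was 0 without any single library other than in9 replicate 1 and after trimmed-mean scaling, where mt-Nd4 had an adjusted p of 0.205, and the count adjusted over the list alone was then 1 without each of those libraries and 0 after the scaling. Without in9 replicate 1 the mitochondrially encoded list held 7 higher genes, the oxidative phosphorylation list 2 higher and 9 lower, and the G1/S list 1 higher and 2 lower.

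The second comparison asked whether genes that miR-9 could regulate directly differed between the groups. Of 30 genes listed from memory as targets of miR-9-5p reported in the literature, 21 were expressed highly enough to test, and 9 had a mean TPM under 1. None of the 21 was called in limma, and 5 were higher and 1 lower at an unadjusted p under 0.05, with none adjusted over the list alone. Without in9 replicate 1, 2 were called higher, and 6 were higher and 1 lower adjusted over the list alone, with 0 in each case without any other single library. Their median log2 fold change was 0.10 (0.16 without in9 replicate 1, 0.06 without in9 replicate 2 and 0.03 after trimmed-mean scaling). Over all tested genes it was 0.06 (0.09, 0.05 and -0.01 in the same order). Of the list, 16 members were positive, a count not compared with the share over all tested genes, and 5 negative. The list was not called by camera (adjusted p = 0.434). The smallest p-values belonged to Socs5 (0.35 ± 0.10 SE), Foxo3 (0.45 ± 0.14), the E-cadherin gene Cdh1 (124 ± 6.12 TPM in LV2 and 141 ± 9.94 TPM in in9) and the vimentin gene Vim (3238 ± 82.7 and 2986 ± 117 TPM), with adjusted p of 0.151, 0.172, 0.201 and 0.222. By the site search below, Vim and another tested member, Meis2, had no miR-9-5p site. Of the listed targets of miR-9-3p, 3 were tested, Rcor1 (0.19), Dnmt3a (-0.12) and Itgb1 (-0.03), and none was called in limma or had an unadjusted p under 0.05.

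The seed of miR-9-5p pairs with ACCAAAG or CCAAAGA in the 3' UTR, and 2436 tested genes had at least 1 such site in their longest annotated 3' UTR against 8516 with none. Genes with a site had a median log2 fold change of 0.08 and genes without a site of 0.06, a difference of 0.0202 that camera did not call at a p under 0.05. Of 100 shuffled seeds of the same bases, 67 gave a difference at least as large, over a range of -0.0182 to 0.0433. The 502 genes with the 8-base site ACCAAAGA differed from genes without a site by 0.0201. Against genes without a site matched on 3' UTR length and expression the difference was -0.00318. Of genes with a site 0.698% were called higher, and of genes without a site 1.03% (Fisher's exact test, two-sided, p = 0.157). Sites of miR-9-3p gave a difference of 0.0251. None of these differences was called by camera. In simulated libraries with the same spread per gene, a shift of 0.1 in the genes with a site was recovered as 0.099. The simulated genes varied independently and no library stood apart. The check therefore does not show what shift could be detected in these data.

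**Figure D4:**
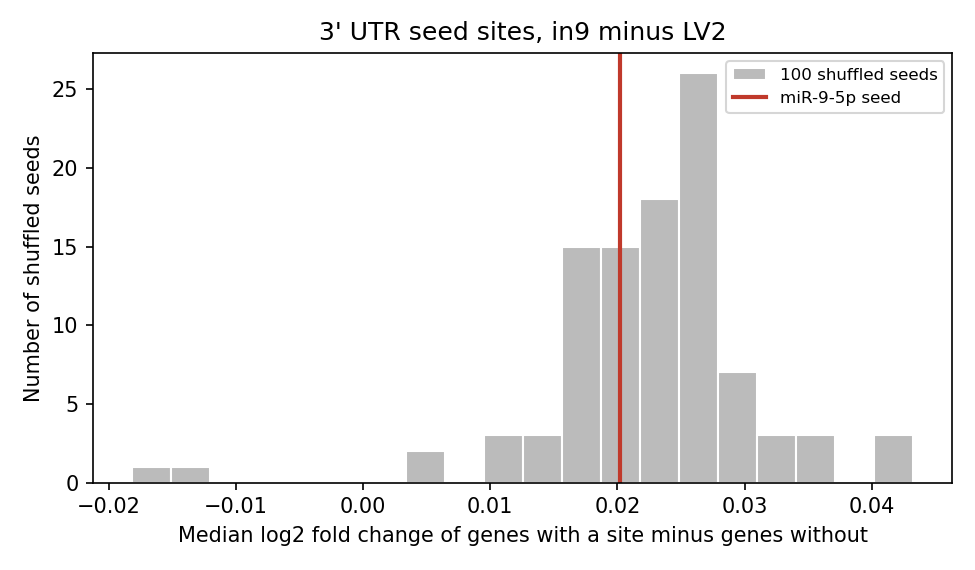
Histogram of the difference in median log2 fold change, in9 minus LV2, between genes with and without a 3' UTR site, for 100 shuffled seeds (grey). The value of the miR-9-5p seed (red line, 0.0202) lies inside their range, with 67 of them at or above it.

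Of 3453 terms tested, 42 were enriched among the higher and 4 among the lower genes by a one-sided Fisher's exact test. Response to bacterium held 14 of the 106 higher genes with a term, out of 108 tested genes (adjusted p = 2.20e-09), and included Lcn2, Nos2, Il6, Ly6a, Gbp2 and Ifit1. Cellular response to interferon-beta held 8 of 43 (adjusted p = 5.55e-06), defense response to virus 11 of 144 (adjusted p = 3.20e-05), and response to hypoxia 9 of 148 (adjusted p = 0.00177). Of the called genes on the hypoxia list this last term held Bnip3 and Ddit4. Its other members were Mmp3, Mmp9, Mmp13, Nos2, Socs3, Plat and mt-Nd4, most of them described above under other lists. Other terms ranked above it, such as response to lipopolysaccharide with 12 of 140 (adjusted p = 5.55e-06). Terms share genes, so they are not separate results. The number of terms was 4, 1 and 0 without LV2 replicates 1, 2 and 3. It was 231, 47 and 1 without in9 replicates 1, 2 and 3. The enrichment test takes genes as independent, so correlation between genes is left out of its p-values. Each of the 4 terms of the lower genes rested on Hspa1a and Hspa1b.

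Markers of other cell types were mostly below the filter. Of the fibroblast markers only Pdgfra was tested, at 5.45 ± 0.992 TPM in LV2 and 8.05 ± 0.307 TPM in in9. Of the macrophage and neutrophil markers Cd68 was at 28.2 ± 0.656 and 37.6 ± 3.63 TPM, S100a8 at 28.2, 19.4 and 12.6 TPM in the 3 in9 libraries against 8.19 ± 1.04 TPM in LV2, and Cd14 at 19.0 ± 2.16 and 16.4 ± 0.570 TPM (SD, n = 3). None of the 9 tested markers over the 5 lists of other cell types was called in limma, with 3 higher at an unadjusted p under 0.05.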

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

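The fit without mitochondrial transcripts and the terms under each alternative were chosen after the result was seen. With a pseudocount of 0.1 (119 higher, 28 lower, 47 terms), quantile normalization (102 higher, 35 lower) and the other alternatives below, each called gene that was still tested kept its direction. Counts depended on the setting, and the cause was not tested. Counts of higher genes, lower genes and terms were 24, 6 and 30 with no filter on low values, where more genes were tested, 150, 45 and 57 at a mean TPM of at least 5, where fewer were tested, 45, 25 and 26 with trimmed-mean scaling, 27, 4 and 52 with no intensity trend, 1166, 523 and 301 with library weights, 313, 84 and 81 with protein-coding genes only, and 143, 21 and 58 without mitochondrial transcripts. At a log2 fold change of at least 1 there were 16 higher and 4 lower genes. Without 1 library at a time there were 6 to 971 higher genes, 1 to 509 lower genes and 0 to 231 terms. The high end of each came without in9 replicate 1, and 135 of the 136 calls were among those genes. Without any other library 8 to 14 genes were called in all.

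With the replicate block 1 gene was higher, 1 was lower, 14 lists were called and 0 terms were enriched. The residuals of samples of the same number correlated at -0.0969, 0.0223 and -0.0461, and not every sample correlated best with its own number (LV2 3 and in9 1 at 0.0981). These values gave no sign of pairing by number. With 3 libraries per group they are too few to exclude a shared batch, on which the labels are silent.

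Of 33 lists, 17 were called, 14 to 19 under the other settings with the preset correlation and 0 with the correlation estimated. The lists of epithelial, mesenchymal, antioxidant, oxidative phosphorylation and integrated stress response genes lost their call under at least 1 setting, and the other 12 called lists kept it under each setting with the preset correlation in which they were tested (the mitochondrially encoded list not without its own transcripts). The mitosis list gained a call, lower, with trimmed-mean scaling, and the lists of angiogenic factors, apoptosis regulators, TGF-beta signalling and fatty acid synthesis gained one, higher, under at least 1 setting. The seed-site difference ranged from 0.0088 to 0.0377, but was -0.0032 against genes matched on 3' UTR length and expression, and it was called under no setting (lowest p 0.0509, without in9 replicate 1). The median of the literature targets ranged from 0.0269 with trimmed-mean scaling to 0.157 without in9 replicate 1. Over all tested genes the median was -0.0105 and 0.0899 under these settings. Of the values of named genes under alternatives, 742 kept direction and side of the threshold, 366 were no longer past it, 68 were newly past it and 1 lost its direction: mt-Atp8 was at 0 after quantile normalization, which gives the most abundant gene the same value in each library. Depth is unknown, so what it limits could not be computed.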

Other observations

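The tests of leukocyte transcripts, of scaling for the shares of the libraries, of in9 replicates 2 and 3, of the summed Hspa1 copies and of the other splits of the samples were chosen after the result was seen. Among gene lists not described above, none was called by camera in the fit used for the report. Apoptosis regulators had a median log2 fold change of 0.14 over 18 genes (adjusted p = 0.0573), and angiogenic factors of 0.13 over 18 (adjusted p = 0.06), where Cxcl5 was called. Genes of TGF-beta and BMP signalling had a median of 0.09 over 24 genes, Notch signalling of 0.13 over 15, Wnt signalling of 0.10 over 17, YAP/TEAD targets of 0.12 over 21, and fatty acid synthesis of 0.12 over 21. Replication-dependent histones had a median of 0.12 over 7 genes. The median over all tested genes was 0.06, and -0.01 after trimmed-mean scaling. With that scaling the medians of these 8 lists, in the order given, were 0.07, 0.06, 0.02, 0.06, 0.03, 0.05, 0.04 and 0.04. In these lists other than that of Cxcl5 no gene was called in limma, and at an unadjusted p under 0.05 there were 5 and 0 (apoptosis), 7 and 1 (TGF-beta), 5 and 1 (Notch), 0 and 1 (Wnt), 5 and 1 (YAP/TEAD), 4 and 1 (fatty acid synthesis) and 0 and 0 (histones) higher and lower genes. Medians of the mitosis (0.02), p53 target (0.04), unfolded protein response (0.04), tumour-initiating (0.01) and housekeeping (0.04) lists turned negative after trimmed-mean scaling, where the mitosis list was called lower (adjusted p = 0.0277, range over the settings up to 0.892). The angiogenic list was called higher after trimmed-mean scaling (adjusted p = 0.0493) and quantile normalization (0.0228). Its range was 0.0113 to 0.173 over the settings with the preset correlation, and it was 0.521 with an estimated correlation. In those 5 lists no gene was called in limma, and 0 and 4, 2 and 1, 2 and 2, 3 and 1, and 4 and 1 were higher and lower at an unadjusted p under 0.05.

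For the rise of the interferon-response list, leukocytes among the in9 cells would bring their abundant transcripts, but the highest in9 mean of 10 such transcripts was 0.19 TPM (Lyz2), 7 of them were listed at 0, and the median rise of the list was 10.96 TPM, which argues against them. Of the fixed macrophage and neutrophil markers Cd68 (28.2 and 37.6 TPM in LV2 and in9) and S100a8 (8.19 TPM in LV2, 12.6 to 28.2 in in9) were higher adjusted over the list alone, and the source of these transcripts was not tested. Removing a trend on gene length, GC and mean expression left a list median of 0.42 (quartiles 0.27 and 0.51) against 0.47 before. Trimmed-mean scaling divides each library by 1 factor, which moves genes nearly alike on the log scale. It took the median over all tested genes from 0.06 to -0.01 and left a list median of 0.39 (quartiles 0.21 and 0.50). Neither the trend nor a common shift of that size accounts for the whole rise. A factor per library cannot show whether the difference in mitochondrial and ribosomal share bears on this list in another way. The labels say neither which group carries the knockdown nor whether the control cells received a vector, so a response to the virus was not tested and stays open.

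The median change of the ribosomal protein genes was smaller in size and uneven between the in9 libraries. None of the 34 was called in limma over all genes, and the list was not called by camera with an estimated correlation (adjusted p = 0.414). Against genes matched on length and mean expression the list was lower by a median of -0.14 (quartiles -0.23 and -0.08), which argues against gene length as the whole cause, though the match was incomplete. The matched genes were less abundant (median 616 against 1642 TPM) and longer (median 1088 against 869 bases). Across genes the log2 fold change rose with gene length (Spearman rho 0.177), so a part of the length trend may remain. Reads moved to ribosomal pseudogenes would raise these, but the summed pseudogenes had an in9 to LV2 ratio of 0.879, near the 0.868 of the genes themselves. Whether the lower values belong to in9 replicates 2 and 3 alone could not be decided: in in9 replicate 1 the list median was -0.08, and 76.5% of its genes lay below all LV2 libraries.

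The fall of Hspa1a and Hspa1b was weighed against 2 explanations. Reads split between the near-identical copies would leave their sum alone, but the sum had an in9 to LV2 ratio of 0.434. A difference in heat-shock activity at harvest that moved heat-shock factor targets by the same fold is argued against by the median log2 fold change of 8 others, -0.0237 (quartiles -0.18 and 0.02). Each of the 8 lay between -0.29 and 0.30, against -1.20 for Hspa1b. Among the abundant ones Hspe1 and Hspa8 were at -0.28 and -0.15, and Hspd1 and Hsp90aa1 at -0.01 and 0.01. A weaker difference that shows mainly in the most inducible genes stays open. Of the genes without a high basal level Dnajb1 was at -0.29 (adjusted p = 0.0861) and Bag3 and Hsph1 were at -0.03 and 0.03. Hspb1 was at 0.30 (adjusted p = 0.546), near the filter with a mean of 1 TPM in LV2.

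The 6 libraries can be split 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 136 genes and the highest other 1, so that 1 of 10 gave as many, and it called 17 lists against 6 (1 of 10) and 46 terms against 0 (1 of 10). The seed-site difference was 0.0202 against 0.0504 in the highest other split, with 6 of 10 as large, and the median of the literature targets 0.102 against 0.171, with 2 of 10 as large. The split that sets LV2 replicate 1 with in9 replicates 2 and 3 gave 2112 genes at an unadjusted p under 0.05 against 2613 for the real one.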
